A study of Homo sapiens with 6 samples.

How the data were processed

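The samples were THP-1 cells transduced with an empty vector or a PTX4 construct, with 3 biological replicates each, all given the same batch in the labels. Per the labels' protocols, total RNA was enriched for mRNA with oligo(dT) beads, fragmented, reverse transcribed and sequenced as pairs of reads. Whether the library kit marked the strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated with certainty. The submitters' processing notes name FastQC 0.11.5, STAR, featureCounts and the genome build GRCh38, with no settings and no version for STAR or featureCounts. The annotation release is not given in the sources used here.

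The authors deposited 3 tables with 78686 rows, one per versioned Ensembl gene. The first holds expected counts, which the authors made, per the submitters' processing notes, by aligning reads with STAR and counting them with featureCounts, and deposited without normalization. Of these deposited values 7.9% are not whole numbers, and the step that made them so is not given in the sources used here. Fractions of that kind arise where a read is divided between genes, so genes with near-identical copies are uncertain. The second deposited table holds TPM, which the authors scaled for gene length and to a sum of 1000000 per library. The third deposited table holds FPKM, scaled by the authors for gene length and depth. No comparison between groups by the authors was used.

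Gene names were matched by Ensembl identifier, which named 61434 identifiers and left 17223 without a symbol. The unnamed identifiers held 0.213% to 0.315% of counts. Coordinates and gene types came from GENCODE release 44 on GRCh38. Genes of the pseudoautosomal regions were listed at both X and Y, and 29 such pairs were summed. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

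Depth ranged from 29670641 to 37718207 expected counts, and the 10 most abundant genes held 5.89% to 7.82%. No 2 libraries agreed within sampling noise: the smallest chi-square per degree of freedom, over genes with 20 or more counts in a pair of libraries, was 6.54, so each library was counted once. Counting intervals and floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules.

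Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F test compared PTX4-OE with EV. Calls needed a Benjamini-Hochberg adjusted p under 0.05. A fold over 2 was a description of size, not a test. Standard errors were taken from the fold change and the F statistic, which understates the error of a gene near 0 in one group, so PTX4 is given with an exact interval on its counts. They also rest on variances that edgeR moderates across genes. Standard errors and intervals therefore do not measure the spread between a gene's own pairs, which can be wider. Normalised CPM values carry the TMM factors.

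The design set at the start had no block. The replicate numbers come from the labels, which do not say what they share. Whether they pair the samples was decided from the correlation of same-numbered libraries' deviations from their group means, PTX4 left out, before the calls of the fits were compared. The correlations were 0.632, 0.130 and 0.699 for numbers 1, 2 and 3, all over the limit of 0.1, although that of number 2 was close to the limit. For unlike numbers they ran from -0.643 to 0.117, so EV replicate 2 with PTX4-OE replicate 1 also passed the limit. The numbers were therefore taken to pair the libraries, and a fit with replicate number as a block is printed beside the one without where it changes a call or moves a count by over 1.5 times.

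There were 34 gene lists, of which 31 had the 5 tested members needed. They covered pentraxins, immune and myeloid functions, the cell cycle, stress, metabolism, the leukaemia fusion programme, other cell types and signs of RNA quality. Lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation. With an estimated correlation, 0 lists were called in either fit, and the smallest adjusted p was 0.115 without blocks and 0.296 with them. That form of camera draws on the few residual degrees of freedom of 6 libraries, so few lists could pass it. For monocyte to macrophage genes with blocks the estimated correlation was -0.023, below the preset. Their camera p still rose from 4.371e-07 to 0.0284 before adjustment. The call of that list with blocks therefore need not have been lost through correlation between genes. With blocks the estimate was also below the preset for other lists, such as NF-kB genes (-0.037). It was far above the preset for mitochondrially encoded mRNAs (0.940), glycolysis (0.227) and fatty acid genes (0.104). For these lists the loss may come from correlation between genes. The rotation test fry, which asks whether a list's genes move one way on balance, called 7 lists with blocks and 0 without. These 7 were the Fc receptor, NF-kB, antigen presentation, monocyte to macrophage, granulocytic precursor, integrated stress response and B cell lists. Of the lists that camera called with blocks, fry did not call immediate early (adjusted p = 0.331), mitochondrial (0.409), adhesion (0.0954), glycolysis (0.502) and fatty acid genes (0.334).

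Genes named in the text followed a rule. It took PTX4, then up to 10 genes per direction with the largest fitted change. These needed an adjusted p under 0.05, an average log2 CPM of 2 or more, non-overlapping groups and an official symbol, which left out pseudogenes and clone or provisional names such as those that start with LINC, LOC or MIR. It added up to 3 called members of each list, or the 2 with the smallest p where none passed. Applying the rule to the fit with blocks, with the same sign in every pair in place of non-overlapping groups, was decided after the data were examined. The lists, the rule, the tests and the first set of alternatives below were chosen before the data were examined.

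The procedure was tested on simulated libraries with the real depths, replicate effects and dispersions, 17323 genes and 200 genes changed by 4 known folds, 50 at each. Without blocks 0, 3, 28 and 47 were recovered at 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 0 unchanged genes were called. With blocks 36, 50, 50 and 50 were recovered and 18 unchanged genes were called, 8.82% of 204 calls. Camera called 1 list in each fit although no list had been changed.

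The first set of alternatives held other scalings (RLE and upper quartile), DESeq2 1.42.0, limma-voom, no filter or a filter of 1 CPM in 3 libraries, PTX4 left out, limma on log2 of TPM or FPKM with a pseudocount of 1 or 0.1, replicate number as a block, and each library left out. The same kinds of alternative with the block were added after the data were examined. So were a correction for GC content and transcript length, the mitochondrial genes left out and each pair left out.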

Results

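RNA was measured in THP-1, a human monocytic leukaemia cell line that carries the MLL-AF9 fusion. The cells had been stably transduced with an empty vector (EV) or with a construct that overexpresses PTX4 (PTX4-OE). PTX4 encodes pentraxin 4, a member of the family of soluble recognition proteins that includes C-reactive protein. Each condition had 3 biological replicates, numbered 1 to 3 in both, and RNA with poly(A) tails was sequenced. The total expected count was 32653460, 29670641 and 32691577 in EV replicates 1 to 3 and 37718207, 31078642 and 37240283 in PTX4-OE replicates 1 to 3. After a filter on low counts, 17627 genes were tested. The single comparison, PTX4-OE against EV, asked which transcripts PTX4 overexpression changes.

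PTX4 itself (ENSG00000251692.8, chromosome 16, 1485886 to 1488981, minus strand, GRCh38, protein coding) separated the groups. Its expected count was 0, 3 and 4 in the EV libraries and 24633, 14398 and 15782 in the PTX4-OE libraries. In deposited TPM this was 0.08 ± 0.07 (SD, n = 3) against 540.4 ± 141.2 (SD, n = 3), and PTX4 ranked 184, 246 and 230 among all genes in PTX4-OE replicates 1, 2 and 3. The ratio of summed counts, scaled for library size, was 6996, with an exact 95% binomial interval of 3395 to 17403. That interval covers counting error only. The fitted log2 fold change was 12.70 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.418e-04), and its exact size depends on the few EV counts. With limma-voom the log2 fold change was 12.97 and the adjusted p was 0.0566. On both sides of the locus, CLCN7, TELO2, IFT140, UQCC4 and CCDC154, chosen after their values were seen, did not pass the test, with log2 fold changes of 0.012, 0.052, 0.097, -0.073 and -0.13. The counts cannot tell transcripts of the construct from those of the chromosomal gene.

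**Figure D1:**
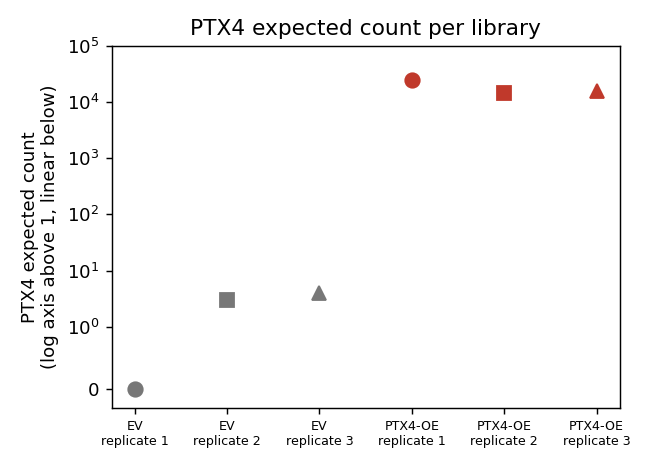
PTX4 expected count in each of the 6 libraries (EV in grey, PTX4-OE in red, marker shape by replicate number), on an axis that is logarithmic above 1 and linear below. The EV libraries lie at 0, 3 and 4 and the PTX4-OE libraries between 14398 and 24633.

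Outside PTX4, most of the genes that passed the edgeR test were moderately lower in PTX4-OE, and after the filter on low counts they passed it only when libraries of the same replicate number were compared as pairs. CHI3L1, a chitinase-like glycoprotein secreted by macrophages (ENSG00000133048.13, chromosome 1, 203178931 to 203186704), went from 61.1 ± 11.9 to 36.6 ± 9.52 CPM (SD, n = 3 each). Its log2 fold change was -0.75, with a standard error of 0.056 and an edgeR adjusted p of 7.621e-06. The myeloid nuclear protein gene MNDA was at -0.52 (SE 0.062) and the peroxidase gene of neutrophil granules, MPO, at -0.54 (SE 0.080). TNF, the inflammatory cytokine, was at -0.35 (SE 0.054). All 4 were lower in each of the 3 pairs. B3GNT7 (-0.48, SE 0.051) and TMEM121B (-0.48, SE 0.054), named after their values were seen, had smaller adjusted p values than MNDA, MPO and TNF. Of the 41 genes called lower, 13 were in any of the gene lists. At an unadjusted p under 0.05 with pairs, 769 genes were higher and 779 lower.

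With the pairs as blocks, 5 genes were higher (PTX4 and 4 others) and 41 were lower, of which FOSB, PRAM1, NPIPP1 and ENSG00000144785 fell by over 2-fold, the last 2 named after their values were seen. NPIPP1 and ENSG00000144785 had 0 counts in every PTX4-OE library and fractional counts in every EV library. Without blocks, PTX4 was the only gene that passed and 0 genes were lower. In that fit 131 genes had an unadjusted p under 0.05, where chance alone would give 881, and DESeq2 without blocks called 2 genes lower and limma-voom 0. The biological coefficient of variation was 0.217 without blocks and 0.055 with them. Every one of the 41 genes had the same sign in all 3 pairs and also a negative log2 fold change without blocks. Both largely follow from calling these genes with pairs, since the fits with and without blocks give similar fold changes, so neither is separate support.

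The falls called with pairs were small for most genes, with a median log2 fold change of -0.48 and the weakest at -0.26. The strongest among genes named by the rule were those of FOSB (-1.95, SE 0.30), a subunit of the AP-1 transcription factor, and PRAM1 (-1.07, SE 0.15), an adaptor protein of myeloid cells. They were followed by SERPINB10 (-0.84, SE 0.14), MS4A3 (-0.84, SE 0.16), DHRS9 (-0.76, SE 0.12), CHI3L1 as given above, GPR84 (-0.72, SE 0.12), DUSP1 (-0.71, SE 0.12), CEACAM6 (-0.65, SE 0.12) and AIF1 (-0.60, SE 0.11). MS4A3 is a membrane protein of myeloid precursors, GPR84 a receptor for medium-chain fatty acids, and AIF1 a calcium-binding protein of macrophages. FOSB (ENSG00000125740.15, chromosome 19, 45467995 to 45475179) stood at 42.8 CPM in EV replicate 3 and at 6.83 and 13.5 CPM in EV replicates 1 and 2. Without the pair of replicate 3 the log2 fold change of FOSB was -1.06, and that of DUSP1 was -0.46. That of PRAM1 was then -0.80, a fall of under 2-fold. PRAM1 stood at 12.4 CPM in EV replicate 3 and at 5.47 and 6.13 CPM in EV replicates 1 and 2. The 4 other genes that rose were APOLD1 (0.38, SE 0.070), IGFBPL1 (0.37, SE 0.063), TRAK2 (0.30, SE 0.053) and MAP1B (0.27, SE 0.048). TRAK2 links mitochondria to kinesin motors and MAP1B binds microtubules.

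**Figure D2:**
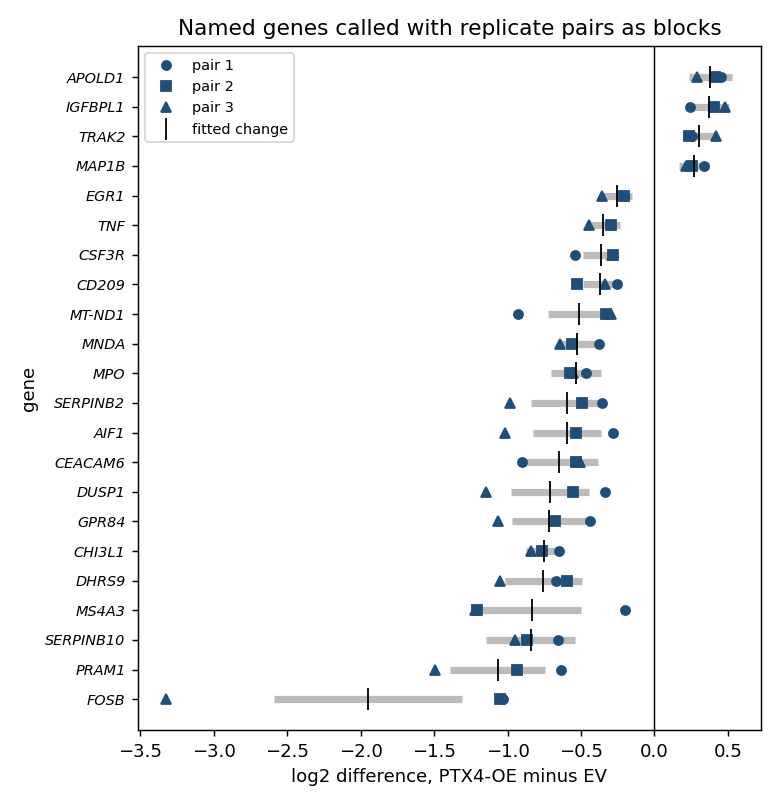
Log2 difference, PTX4-OE minus EV, for the named genes called with pairs as blocks, PTX4 left out, with circles, squares and triangles for pairs 1, 2 and 3, a black tick for the fitted change and a grey bar for its 95% confidence interval. FOSB has the widest spread, with pair 3 at -3.32 and pairs 1 and 2 at -1.03 and -1.05.

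The calls depended on the set of pairs. Without the pair of replicate 2, 31 of the 45 genes other than PTX4 lost their call, and 9 genes were higher and 23 lower. The median log2 fold change of the 41 genes was -0.48 with and without that pair. Without the pair of replicate 1, 30 genes were higher and 58 lower, and without that of replicate 3, 41 and 167. CHI3L1 was the only one of the 45 that passed under all 14 alternatives run with blocks. On log2(TPM + 1) with blocks, CHI3L1 was the 1 gene called lower. The 95% confidence interval lay within 2-fold in either direction for 75.5% of genes without blocks and for 86.2% with them.

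Genes of monocyte to macrophage differentiation were called lower as a list by camera with a preset correlation, and not with an estimated one. Fry also called the list lower with blocks (adjusted p = 0.0165) and not without (0.784). With pairs, 4 of 33 tested members fell, 0 rose and 29 did not pass: CHI3L1, MNDA, CSF3R (-0.37, SE 0.056), the receptor for G-CSF, and CSF1R (-0.30, SE 0.056), the receptor for M-CSF, which is named after its value was seen. There were 6 that fell when adjusted over the list alone. The list median was -0.059 with blocks and -0.029 without, and that of each pair was negative (-0.058, -0.080 and -0.062). Camera, with a preset correlation of 0.01, gave an adjusted p of 4.517e-06 with blocks and 0.0419 without. With an estimated correlation the adjusted p was 0.296 and 0.396, so this call was lost. With blocks that correlation was -0.023, below the preset, so the loss there came from the few degrees of freedom of that form of camera. The call was also lost without blocks when EV replicate 1, PTX4-OE replicate 2 or PTX4-OE replicate 3 was left out (adjusted p = 0.574, 0.587 and 0.0761), and the median without EV replicate 1 was 0.049.

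The NF-kB and antigen presentation lists were called lower by camera with a preset correlation, and not with an estimated one. Fry also called them lower with blocks (adjusted p = 0.0165 and 0.0475) and not without (0.391 and 0.121). Of 28 tested NF-kB target and cytokine genes, TNF and SERPINB2 (-0.59, SE 0.11), an inhibitor of plasminogen activators, fell with pairs and 0 rose, and 22 had a negative log2 fold change. A count of 5 fell when adjusted over the list alone. The median was -0.098, with a camera adjusted p of 9.473e-05 with blocks and 6.644e-05 without, and of 0.296 and 0.115 with an estimated correlation. Of 23 antigen presentation genes 20 had a negative log2 fold change and 0 passed the test over all genes, against 2 that fell when adjusted over the list alone. HLA-DRB1 and HLA-DRB5, which encode class II beta chains and are similar in sequence, were at -0.33 (SE 0.072) and -0.36 (SE 0.13). The list median was -0.14, with a camera adjusted p of 1.476e-05 with blocks and 9.452e-07 without, and of 0.296 and 0.115 with an estimated correlation.

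FOSB, DUSP1, a phosphatase that switches off MAP kinases, and EGR1 (-0.26, SE 0.050), a zinc finger transcription factor, were the 3 of 35 immediate early genes that fell with pairs, and 0 rose. FOS itself was at -0.60 (SE 0.12, adjusted p = 0.0606), with -0.16, -0.44 and -1.19 in pairs 1, 2 and 3. When adjusted over the list alone, 8 fell. The median was -0.056 and the camera adjusted p was 2.960e-04 with blocks and 7.986e-04 without. With an estimated correlation these became adjusted p = 0.354 and 0.154. Fry did not call the list with blocks (adjusted p = 0.331). Without EV replicate 3, the library in which FOSB was high, the adjusted p of the fit without blocks was 0.111 and the median -0.076. In the short list of granulocytic precursor genes, MPO and CEACAM6, a cell surface adhesion molecule, fell among 6 tested members and 0 rose, also when adjusted over the list alone. Its median was -0.094 and its camera adjusted p 9.473e-05 with blocks and 0.0012 without, or 0.296 and 0.150 with an estimated correlation. Without PTX4-OE replicate 3, the adjusted p without blocks was 0.0646 and the median -0.16. It was still called, with medians of -0.16, -0.23, -0.21 and -0.16, without EV replicate 1, EV replicate 3, PTX4-OE replicate 1 and PTX4-OE replicate 2. Fry called the granulocytic precursor list lower with blocks (adjusted p = 0.0475) and not without (0.391).

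CD209, a lectin that binds pathogens, was the 1 of 15 Fc receptor and phagocytic genes that fell with pairs (-0.37, SE 0.055), and 3 fell and 1 rose when adjusted over the list alone. FCGRT, the neonatal Fc receptor, was at -0.28 (SE 0.064). The list median was -0.032, the camera adjusted p 0.0126 with blocks and 0.0227 without, and with an estimated correlation the adjusted p was 0.406 and 0.233. Without blocks the list lost its call when EV replicate 1, PTX4-OE replicate 2 or PTX4-OE replicate 3 was left out (adjusted p = 0.230, 0.103 and 0.260), with medians of -0.068, -0.043 and -0.077. It was still called without EV replicate 2, EV replicate 3 or PTX4-OE replicate 1 (medians -0.058, -0.087 and -0.083), and with blocks without the pair of replicate 1 or 3 (-0.10 and -0.071). Fry called the Fc receptor list lower with blocks (adjusted p = 0.0475) and not without (0.423). Of 29 adhesion and migration genes 0 passed over all genes, and adjusted over the list alone 6 fell and 2 rose. PECAM1, which joins leukocytes and endothelium, was at -0.24 (SE 0.054) and PXN, the focal adhesion adaptor paxillin, at 0.20 (SE 0.064). The adhesion list had a median of -0.012 and a camera adjusted p of 0.0144 with blocks and 0.135 without. With an estimated correlation its adjusted p was 0.406 and 0.506, and without the pair of replicate 2 it was 0.0635, with a median of -0.064. With blocks, its median was 0.0040 with no filter and 0.0068 on log2(TPM + 1).

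The list of integrated stress response and amino acid supply genes was called higher by camera with a preset correlation, and not with an estimated one. Fry also called it higher with blocks (adjusted p = 0.0475) and not without (0.121). Of 34 tested members 33 had a positive log2 fold change and 25 were higher in all 3 pairs, while 0 passed the test over all genes and 1 rose when adjusted over the list alone. PSPH, the last enzyme of serine synthesis, was at 0.23 (SE 0.051) and CHAC1, which degrades glutathione, at 0.18 (SE 0.054). The list median was 0.091. Its camera adjusted p was 3.841e-09 with blocks and 6.644e-05 without, and with an estimated correlation 0.296 and 0.115. Glycolysis and hypoxia genes (median 0.055) and fatty acid genes (median 0.050) passed camera only with blocks, with adjusted p = 0.0073 and 0.0091. Without blocks these were 0.0730 and 0.0657, and with blocks and an estimated correlation the adjusted p was 0.533 and 0.477. Neither passed without the pair of replicate 3 (adjusted p = 0.586 and 0.201), and in pair 2 their medians were -0.021 and -0.030. Over the alternatives run with blocks, their medians ran from 0.0095 to 0.106 and from 0.019 to 0.077. Of their 34 and 29 tested members 0 passed over all genes. ALDOC, a glycolytic aldolase, was at 0.42 (SE 0.14), with -0.054, 0.19 and 1.04 in pairs 1, 2 and 3, and PPARA, a lipid-sensing nuclear receptor, at 0.28 (SE 0.067). Of the glycolysis genes 0 passed, and 1 fatty acid gene rose, when adjusted over the list alone.

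The 13 mitochondrially encoded mRNAs, which served as a sign of RNA quality, were lower in PTX4-OE, mainly in one library. They and the other mitochondrial genes took 2.79% of counts in PTX4-OE replicate 1 and 4.75% to 5.91% in the other 5 libraries. With pairs, MT-ND1, a complex I subunit, fell (-0.52, SE 0.098, and -0.31 without the pair of replicate 1), the other 12 did not pass, and adjusted over the list alone 10 fell. The median log2 difference was -0.83 in pair 1, -0.067 in pair 2 and -0.17 in pair 3. Camera gave an adjusted p of 3.455e-15 with blocks and 2.229e-08 without, and of 0.444 and 0.396 with an estimated correlation. That correlation was 0.940 with blocks and 0.821 without, far above the preset of 0.01. Without PTX4-OE replicate 1 and without blocks, the median was -0.018 and the adjusted p 0.432. With blocks and without the pair of replicate 1, the list was still called, with a median of -0.14 and an adjusted p of 8.790e-06. With the mitochondrial genes left out of the fit with pairs, 5 genes were higher and 41 lower, and 44 of the earlier calls remained.

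**Figure D3:**
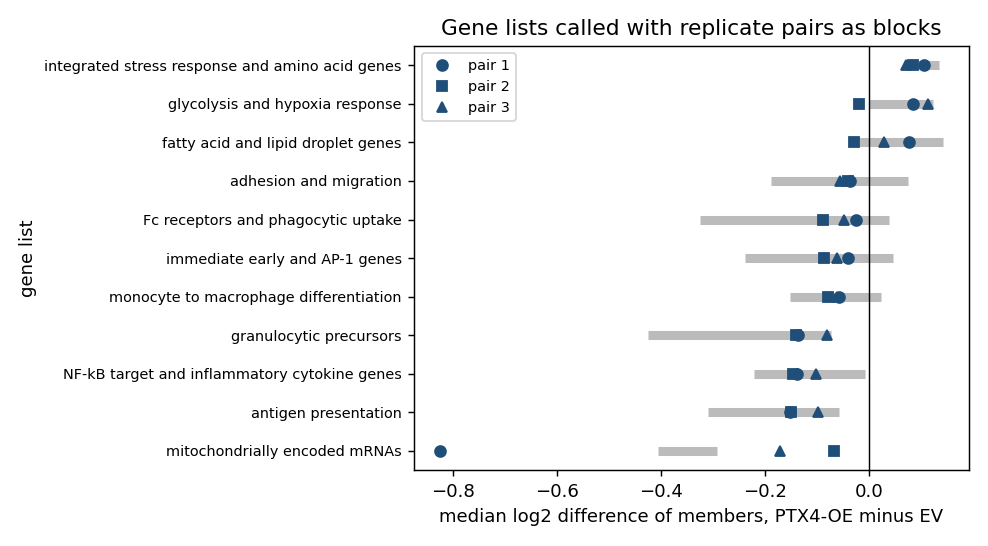
Median log2 difference of the tested members of each gene list called by camera with pairs as blocks, PTX4-OE minus EV, with circles, squares and triangles for pairs 1, 2 and 3 and grey bars for the interquartile range of the members' fitted changes. Mitochondrially encoded mRNAs reach -0.83 in pair 1, and every other list median lies closer to 0.

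Lists for B cells and for pentraxins other than PTX4 were called higher by camera without blocks only. Fry called the B cell list higher with blocks (adjusted p = 0.0233). Of the B cell genes 6 were tested, with a median of 0.30, and PAX5, a B lineage transcription factor, was at 0.76 (SE 0.16, adjusted p = 0.0668 with blocks). Over all genes 0 B cell genes passed, and 1 rose when adjusted over the list alone. The B cell list had a camera adjusted p of 0.0377 without blocks and 0.0835 with them, and with an estimated correlation 0.264 and 0.477. The list named pentraxins other than PTX4 (6 tested, 0 passed over all genes or adjusted over the list alone, median 0.25) had camera adjusted p = 0.0312 without blocks and 0.0835 with them, and 0.268 and 0.477 with an estimated correlation. Its members are not all pentraxins, since it also holds the receptor genes ADGRG6 and ADGRD1. NPTXR was at 0.19 (SE 0.092). ADGRG6, with only 14 to 44 counts per library, was at 0.55 (SE 0.34). Both lists lost their call without blocks when PTX4-OE replicate 3 was left out (adjusted p = 0.323 for B cells and 0.468 for pentraxins). The B cell list also lost it without EV replicate 1 (adjusted p = 0.221), and the pentraxins without EV replicate 3 (adjusted p = 0.111). Without blocks the medians were 0.31 for B cells and 0.21 for pentraxins. Over the first set of alternatives they ran from 0.17 to 0.49 and from 0.052 to 0.32. The 7 tested epithelial markers had a median of 0.27 (adjusted p = 0.0548 with blocks), and 1 rose when adjusted over the list alone. T and NK cell, erythroid and fibroblast lists had 3, 1 and 4 tested members, too few for the test, with medians of -0.12, 0.043 and 0.12.

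The other lists were not called in either fit. With pairs, the median log2 fold change was -0.025 for type I interferon genes, where the test pointed up (adjusted p = 0.589), and 0.038 for cell cycle genes (adjusted p = 0.0632). It was -0.028 for complement, -0.032 for pattern recognition, -0.072 for alternative activation, of which CD209 fell, and -0.029 for matrix and proteases. It was 0.052 for cell cycle inhibitors, 0.022 for apoptosis regulators, 0.046 for the unfolded protein response and 0.011 for oxidative stress. Cholesterol biosynthesis stood at 0.043, cholesterol efflux at -0.0027 and nuclear-encoded oxidative phosphorylation at 0.0080. Genes of the MLL-AF9 programme stood at 0.033, lysosome genes at -0.0073, ribosomal protein genes at 0.016 and replication-dependent histone genes at 0.10. For apoptosis regulators the mean was -0.0065, of the other sign than the median and the test. Among the members of these lists CD209 alone passed over all genes. When adjusted over the list alone, 1 gene each rose among matrix and MLL-AF9 genes, and 1 each fell among matrix, cell cycle, cholesterol efflux and alternative activation genes. FBN1, the matrix protein fibrillin-1, was at 0.44 (SE 0.12) and FN1, fibronectin, at 0.46 (SE 0.36). Of 48 cell cycle genes 37 were positive, with CDT1, a replication licensing factor, at 0.13 (SE 0.048) and CCND3, cyclin D3, at -0.25 (SE 0.060). Of 26 MLL-AF9 genes 21 were positive, with the homeobox gene HOXA5 at 0.28 (SE 0.17) and FLT3, a receptor kinase of precursor cells, at -0.30 (SE 0.11). HOXA5 stood at 0.15, 0.77 and -0.041 in pairs 1, 2 and 3.

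Libraries grouped by replicate number more than by PTX4. The first principal component held 57.8% of the variance of log2 CPM, with replicates 1 at -36.4 (EV) and -52.4 (PTX4-OE), replicates 2 at -5.83 and 2.99, and replicates 3 at 46.8 and 44.8. The expression of 9089 genes (51.6%) differed between replicate numbers (edgeR, adjusted over all tested genes).

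**Figure D4:**
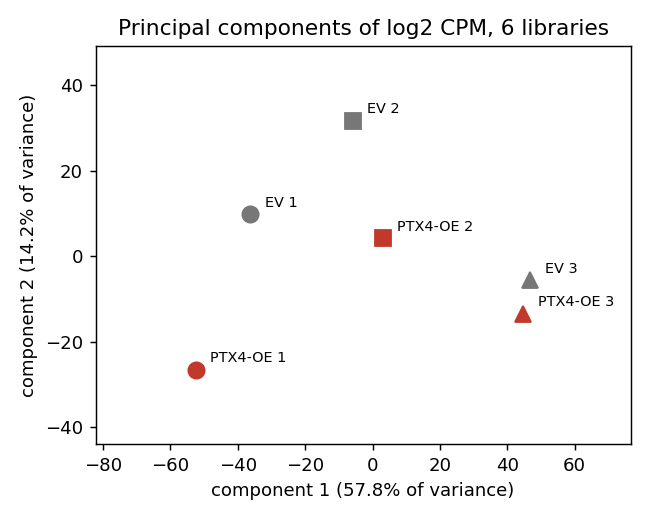
First and second principal components of log2 CPM for the 6 libraries, holding 57.8% and 14.2% of the variance, with EV in grey and PTX4-OE in red. Libraries of the same replicate number lie close together along the horizontal axis.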

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

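Alternatives that add a further change to the replicate block were chosen after the results were seen, and the others were not. Without blocks, 1 gene higher and 0 lower was the result of RLE and upper-quartile scaling, of the 1 CPM filter and of leaving out each library. DESeq2 called 2 genes lower, both by over 2-fold, and 5 lists higher. With limma-voom 0 genes were higher, 0 by over 2-fold, and PTX4 had a log2 fold change of 12.97 (adjusted p = 0.0566, the highest of its alternatives, with 1.262e-94 by DESeq2 the lowest). With no filter 1 gene was lower, by over 2-fold. With PTX4 left out 0 genes were higher and 0 by over 2-fold. On log2(TPM + 1) and log2(FPKM + 1) 2 genes were higher, PTX4 and ENSG00000307158, both by over 2-fold, and 1 list was higher. On log2(TPM + 0.1) 1 list was higher, and on log2(TPM + 1) with no filter 1 was higher and 2 lower. The replicate block gave 5 genes higher and 41 lower, 4 of these by over 2-fold, and of these 46 genes PTX4 was the only one called by edgeR with the same filter and no block. Leaving out each library gave 4 to 10 lists higher and 5 to 12 lower. It turned the sign of 6 genes that were never called, whose log2 fold changes ran from -0.29 to 0.45 (ITGA2B), -0.47 to 0.069 (COL1A1), -0.033 to 0.24 (NDUFA1), -0.044 to 0.23 (ATP5F1D), -0.11 to 0.41 (MS4A4A) and -0.0073 to 0.39 (SCD). With the block, upper-quartile scaling gave 3 genes higher and 27 lower. DESeq2 gave 8 and 26, with 0 lower by over 2-fold, and left 7703 genes with an adjusted p. With limma-voom 14 genes were higher, 2 by over 2-fold, and 6 lists were higher. With no filter 106 were higher and 190 lower, 20 and 25 by over 2-fold, and 8 lists were higher. The 1 CPM filter left 2 genes lower by over 2-fold, and leaving PTX4 out gave 0 higher by over 2-fold and 8 lists higher. The GC and length correction gave 5 lists higher. On log2(TPM + 1) and log2(FPKM + 1) with the block 2 genes were higher, both by over 2-fold, and 1 lower, with 0 lower by over 2-fold, and 6 and 5 lists were higher. Without each pair in turn, genes higher ran from 9 to 41, lower from 23 to 167, higher by over 2-fold from 7 to 15, lower by over 2-fold from 7 to 21, and lists higher from 2 to 7. The cause of these moves was not tested, except that leaving out PTX4 or a library removes what it held. Without blocks, the monocyte to macrophage and B cell lists lost their call with limma-voom, and the Fc receptor and granulocytic precursor lists with no filter. On log2(TPM + 1) with no filter 7 lists lost theirs, NF-kB and immediate early genes among them. With the block, adhesion genes lost theirs with no filter and on log2(FPKM + 1). Antigen presentation and integrated stress response genes were called in every alternative run without blocks and in every one with them, at the preset correlation only (adjusted p = 0.115 and 0.296 for both lists with an estimated correlation). Depth limits the fold of PTX4, since its EV libraries hold 0, 3 and 4 counts.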

Other observations

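The tests of the replicate axis, of the mitochondrial mRNAs and of the genes at 0 were chosen only after the results were seen. Those of GC content and depth were chosen after the data were examined but before their own results. Large gene groups differed between replicate numbers in EV and PTX4-OE libraries. Between replicates 3 and 1, with group in the model, 4548 genes were higher and 5074 lower in replicates 3 (edgeR, adjusted p under 0.05). Cell cycle genes had a median log2 difference of -0.92, with -0.89 among EV and -0.93 among PTX4-OE libraries. Type I interferon genes were at -0.93 (EV -1.19, PTX4-OE -0.67) and nuclear-encoded oxidative phosphorylation genes at -0.57. Examples are IFI6 (-2.56), OAS3 (-1.90) and SIGLEC1 (-1.91), which respond to interferon, and TFRC, the transferrin receptor (-1.64). MALAT1, a nuclear long noncoding RNA, was higher (1.67), as was ZNF117 (1.93), and over 3054 long noncoding genes the median was 0.41 among EV and 0.55 among PTX4-OE libraries. Mitochondrially encoded mRNAs, the sign of RNA quality, had a median of 0.49 (EV 0.13, PTX4-OE 0.91), and epithelial markers one of 1.12 (EV 1.15, PTX4-OE 0.93). Camera gave adjusted p = 3.242e-46 for cell cycle and 3.992e-18 for interferon genes, and with an estimated correlation no list passed (adjusted p = 0.659 for both). These genes were chosen after their values were seen.

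Other transcripts were among the genes called lower with pairs, outside those named by the rule and picked after their values were seen. MIR223HG, the host transcript of a microRNA of granulocytes and monocytes, was at -0.55 (SE 0.075), and MIR222HG at -0.63 (SE 0.11). ALOX5AP, which leukotriene synthesis requires, was at -0.59 (SE 0.10), LST1 at -0.43 (SE 0.076), the IL-17 receptor gene IL17RA at -0.34 (SE 0.051), and GRN, the progranulin gene, at -0.27 (SE 0.050).

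With pairs, 41 genes were called lower in PTX4-OE. After a correction for GC content and transcript length they kept 103% of their median log2 fold change, and 38 stayed called, and with each pair thinned to equal depth they kept 101%. The shift of the PTX4-OE libraries along the replicate axis gives -2.32% of that median. The correction argues against GC or length bias as the whole cause. The mean shift along the axis was -3.08, where scores ranged over 99.2, so its share was bound to be small. It shows only that the groups differ little in mean position on that axis, and it decides nothing further. Thinning leaves a fold change the same on average, so it cannot decide on depth. The 4 ways to exchange EV and PTX4-OE within pairs are too few for a share under 0.05: the real one called 46 genes and the highest other 5 (1 of 4 as large), and for lists 11 against 7 (1 of 4). An effect of PTX4, culture differences tied to each transduced population and some false calls stay open. In simulated data 8.82% of 204 calls were false, but most of those calls were genes changed on purpose. The simulated libraries were also built with the replicate effects, so they did not test whether the replicate numbers pair the real libraries. That share is therefore no estimate of the false share among the 46 real calls.

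Without blocks the 10 splits of the 6 libraries into 3 and 3 are also too few for a share under 0.05. The real split called 1 gene and the highest other 0 (1 of 10 as large). That gene was PTX4 itself, and with PTX4 set aside all 10 splits called 0 genes. For lists the real split called 10 and the highest other 12 (3 of 10 as large). Both other splits with 10 or more lists part a single pair and place both libraries of replicate 1 on one side, whereas the real split parts all 3 pairs.

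Mitochondrially encoded mRNAs may be lower in PTX4-OE because of replicate 1 alone, or in all pairs to a small degree. The median was -0.83 in pair 1, with all 13 lower, -0.067 in pair 2, with 9 lower, and -0.17 in pair 3, with all 13 lower. Pair 3 argues against a difference in replicate 1 alone and pair 2 does not, so the 2 readings cannot be told apart with one library per group in each pair. A general fall of respiratory chain transcripts is argued against by the nuclear-encoded list, whose median was 0.0080 with an interquartile range of -0.021 to 0.042. RNA quality per library was not measured in the files used here.

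The pseudogene NPIPP1 and the gene ENSG00000144785, which overlaps CS and CNPY2 on the same strand, were at 0 in every PTX4-OE library. Their EV counts were 44.81, 83.26 and 31.76, and 27.28, 12.38 and 21.52. Scaled for depth, the means of these counts were 20.2-fold and 7.48-fold higher than a floor of 3 counts per PTX4-OE library. All these EV counts are fractional, so reads shared with similar or overlapping genes are a candidate explanation. Summed over 24 genes of the NPIP family the counts were -2.22 standard errors from no change, and over CS, CNPY2 and the overlapping gene 0.23. A full loss of the 2 genes' counts would move these sums by 0.11 and 0.049 standard errors, so the limit of 2 standard errors set for them was a poor one, as was seen only afterwards, and this stays open.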
